A study of Mus musculus with 6 samples.

How the data were processed

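Total RNA of E14.5 mouse palatal shelves was extracted with a ReliaPrep kit (Promega) and sequenced in 3 control and 3 KO libraries, per the labels' protocols. The deposited values are FPKM, fragments scaled by gene length and library size by the authors, in 1 table of 55631 Ensembl gene IDs by 6 libraries. The unit comes from the name of that table. The submitters' processing notes name the genome build mm10 and DESeq2 version 1.5.2. The aligner, the counter, the annotation release and the strand setting are not given in the sources used here. The smallest value above 0 was between 0.100 and 0.118 FPKM in each library. Values showed no steps of 1 read, so depth is unknown and no counting interval is given. Of 85 protein-coding ribosomal protein genes, 2 were listed at 0 in all libraries, the tissue-restricted Rpl10l and Rpl3l, and the others were above 0 in all of them.

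Libraries were assigned to groups by their titles, and columns to libraries by the library names in the labels. All 6 sample columns were used. Gene symbols and coordinates were taken from the GENCODE annotation of GRCm38 by gene ID. Of the IDs, 50824 matched and 4807 did not, 210 of the latter among the tested genes, which could not be named. No pair of libraries held identical values, and correlations across genes between libraries on the log2 scale lay between 0.982 and 0.993.

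Values were analysed as log2(FPKM + 1) with limma version 3.58.1 in R version 4.3.3. Genes with a mean of at least 1 FPKM over the 6 libraries were kept. A linear model with genotype as its only term was fitted with lmFit and eBayes with a trend. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the fixed lists, with an estimated correlation and fry beside it. The 36 fixed lists, the design, the alternatives and the rule for named genes were set before the data were examined. A further 5 lists were written after the values had been seen. They cover interferon-response genes, class I antigen presentation, interferons with their receptors and sensors, pancreatic acinar enzymes and oestrogen receptor targets, and their list p-values are unadjusted. Single members of the acinar list are not reported here.

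The rule named Bcar1, Nedd9, Efs and Cass4, and up to 12 called genes per direction with the largest fold change and no overlap between groups. Where fewer than 10 genes in a direction met this, it was filled up to 10 with the genes of smallest p among those without overlap and with an absolute log2 fold change of at least 0.58. It added up to 4 members with the smallest p from each described list, or up to 2 where a list was not shifted, and Xist and Ddx3y. Predicted genes, Rik genes and pseudogenes were skipped in choosing by fold change and p. There were 4 such genes among the calls.

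The model was tested on simulated values for the same 14714 genes, with 200 genes changed by known amounts. It recovered 52.2% of genes changed by 0.5 on the log2 scale, 94.0% of those changed by 1 and 98.5% of those changed by 2, and 6.9% of its calls were false. With no gene changed it called 0. On 20 simulated lists, the list test called all 5 that were shifted by 0.5 and 0 of the others. The simulated genes were drawn independently of each other, so this does not cover lists whose members vary together. Nor does it cover differences between samples that many genes share, so the shares of false calls hold only without these. In the real libraries a split that did not follow genotype called 548 genes. The estimated correlation of real lists was 0.74 for skeletal muscle and 0.69 for cartilage genes.

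Alternatives were pseudocounts of 0.1 and 0.01, no filter, filters at a mean of 0.1 and 5 FPKM, quantile normalization, median-of-ratios scaling, rescaling to TPM, eBayes without trend and with robust estimation, library weights, the replicate number as a block, the sex of the embryo as a covariate, and each library left out in turn. Alternatives that need counts were not run, because the values are FPKM.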

Results

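RNA was sequenced from the palatal shelves of E14.5 mouse embryos, the stage at which the shelves of a normal embryo lift and meet to form the roof of the mouth. There were 2 groups of 3 libraries. The control embryos carried loxP-flanked alleles of the gene for p130Cas, an adaptor protein of integrin adhesion sites, and no Cre label. The KO embryos carried the same alleles and a CAG-Cre transgene. The series asks which transcripts change when p130Cas is lost, in a mutant with a cleft palate. Expression was given as FPKM for 55631 genes, of which 25387 were above 0 in at least 1 library. The 14714 genes with a mean of at least 1 FPKM were tested. Each library had between 21500 and 21869 genes above 0, and FPKM summed to between 384979 and 424993 per library. The number of reads behind a value is unknown. The labels do not say whether the embryos of a group came from separate litters, so p-values measure only the spread between these samples. That spread may be technical in part, though KO replicate 2 differed in sex from the other KO libraries and so came from another embryo.

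The deleted gene was looked at first, as a check of the labels. Bcar1 (ENSMUSG00000031955), which encodes p130Cas, lies on chromosome 8 from 111710474 to 111743809 on the minus strand of GRCm38. It stood at 1.80, 1.97 and 2.09 FPKM in control replicates 1 to 3 and at 1.69, 1.69 and 1.31 FPKM in KO replicates 1 to 3. All 3 KO values lay below all 3 control values, and the KO mean was 19.8% lower. The log2 fold change of FPKM + 1 was -0.21 ± 0.11 (SE), which did not pass in limma (adjusted p = 1.00). The exact two-sided permutation test gave p = 0.1, the smallest that the 20 assignments of 6 libraries allow. A value for the whole gene can include exons outside the loxP sites, so it is a weak check and does not measure recombination. Of the other Cas family genes, Nedd9 had a log2 fold change of 0.11 ± 0.10 (SE) and Efs of -0.10 ± 0.08 (SE), and neither passed. Cass4 was listed at 0 in all libraries except control replicate 2, at 0.210 FPKM, and was not tested.

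**Figure D1:**
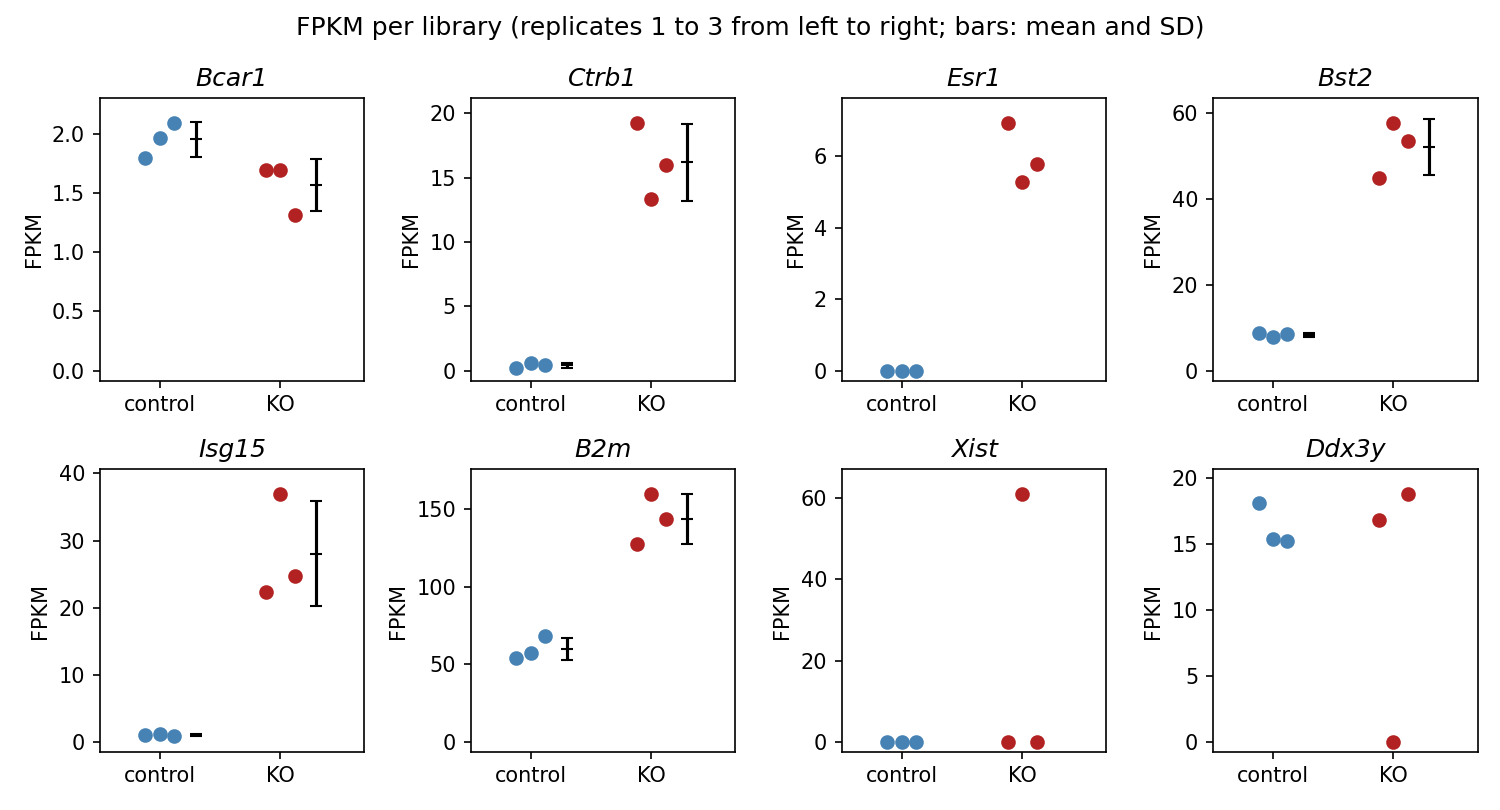
FPKM of 8 genes in each of the 6 libraries, controls in blue and KO in red, with the group mean and SD in black for genes above 0 in all libraries. Bcar1 lay between 1.31 and 1.69 FPKM in KO and between 1.80 and 2.09 FPKM in control libraries, while Ctrb1, Esr1, Bst2, Isg15 and B2m were far apart between the groups.

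The KO shelves carried higher levels of genes known from the response to interferons, the cytokines that cells release on sensing virus. Isg15 (ENSMUSG00000035692), a ubiquitin-like protein, rose from 1.05 ± 0.0950 to 28.0 ± 7.82 FPKM (SD, n = 3 each), a log2 fold change of 3.79 ± 0.17 (SE; limma, adjusted p = 1.16e-04). Bst2, or tetherin, which holds budding virus at the cell surface, rose from 8.39 ± 0.511 to 52.1 ± 6.49 FPKM, a log2 fold change of 2.49 ± 0.10 (SE; limma, adjusted p = 1.14e-04). In limma, 48 genes were higher and 1 was lower in KO at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 307 higher and 283 lower genes, where chance alone gives 736 in all. Of the 48 genes, 39 had a log2 fold change above 1. The groups did not overlap for any of the 49 called genes, nor for 9.06% of all tested genes, where chance gives 10%.

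Other genes had large changes too. Oasl2 rose from 1.16 ± 0.322 to 11.0 ± 1.38 FPKM, and Usp18, the protease that removes Isg15 from proteins, from 0.403 ± 0.142 to 6.78 ± 1.75 FPKM. Rtp4 rose from 1.32 ± 0.515 to 10.6 ± 0.667 FPKM and Ifi27l2a from 1.40 ± 0.0825 to 22.4 ± 9.41 FPKM. Irf7, a transcription factor that drives interferon genes, rose from 0.476 ± 0.276 to 6.14 ± 1.81 FPKM. H2-K1 and H2-D1, the class I molecules that present peptides at the cell surface, rose from 2.45 ± 0.306 to 18.8 ± 6.47 FPKM and from 5.78 ± 0.0739 to 29.8 ± 8.79 FPKM. Ifit1, which binds foreign RNA, rose from 0.157 ± 0.0259 to 4.30 ± 1.98 FPKM (limma, adjusted p = 0.0230). Its call was lost without control replicate 1, 2 or 3 (adjusted p = 0.0990, 0.126 and 0.161) and without KO replicate 2 or 3 (adjusted p = 0.0764 and 0.0622), in a range over all alternatives from 7.89e-04 to 0.161. H2, Oas and Ifi27 genes have near-identical relatives, so the split of reads between members is uncertain.

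Ctrb1 and Esr1 were also among the 12 named genes with the largest increases. Ctrb1 (ENSMUSG00000031957), which encodes the pancreatic protease precursor chymotrypsinogen B1, rose from 0.414 ± 0.212 to 16.2 ± 2.98 FPKM (SD, n = 3 each), a log2 fold change of 3.60 ± 0.16 (SE; limma, adjusted p = 1.16e-04). It lies on chromosome 8 from 111686519 to 111691010 on the minus strand of GRCm38, 19.5 kb downstream of Bcar1 on the same strand. The 14 other tested genes within 500 kb of Bcar1 did not pass, and the largest absolute log2 fold change among them was 0.22, for Chst5. Esr1 (ENSMUSG00000019768), which encodes oestrogen receptor alpha, lies on chromosome 10 from 4611593 to 5005614 on the plus strand. It was listed at 0 in the 3 control libraries and stood at 6.94, 5.28 and 5.80 FPKM in KO replicates 1 to 3 (limma, adjusted p = 1.14e-04).

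**Figure D2:**
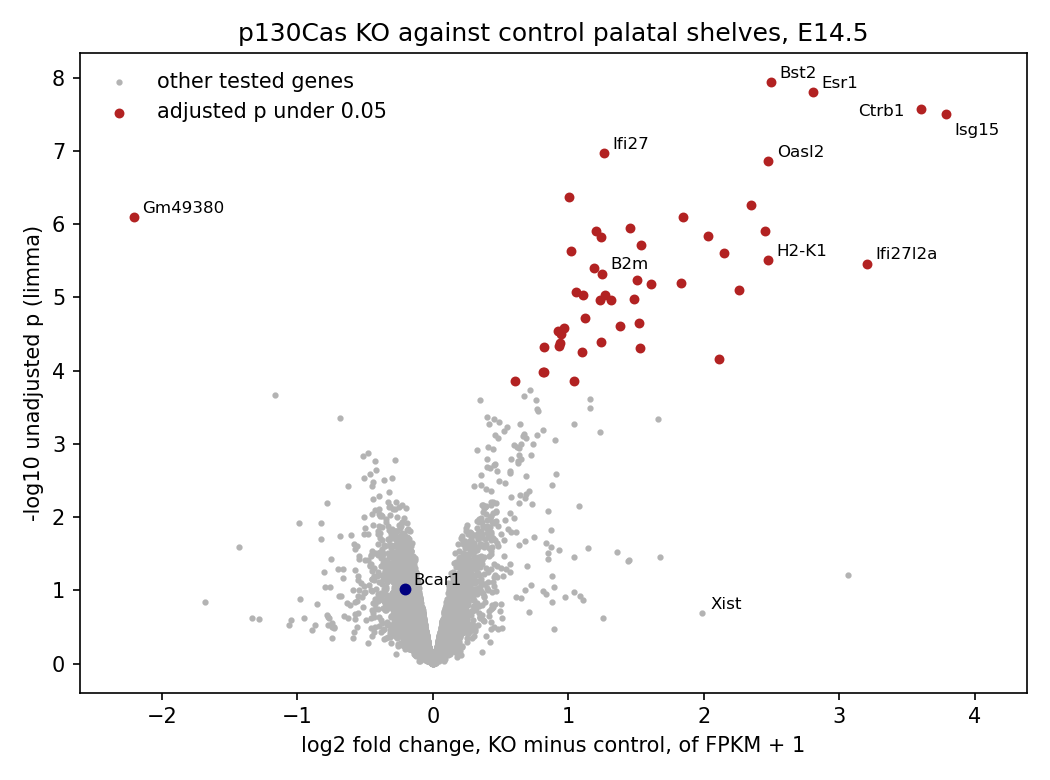
Each point is 1 of 14714 tested genes, with the log2 fold change of FPKM + 1 (KO minus control) on the x axis and the negative log10 of the unadjusted limma p on the y axis, red where the adjusted p was under 0.05 and blue for Bcar1. Of the 49 red points 48 lie to the right, and Bcar1 lies near the centre at -0.21.

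**Figure D3:**
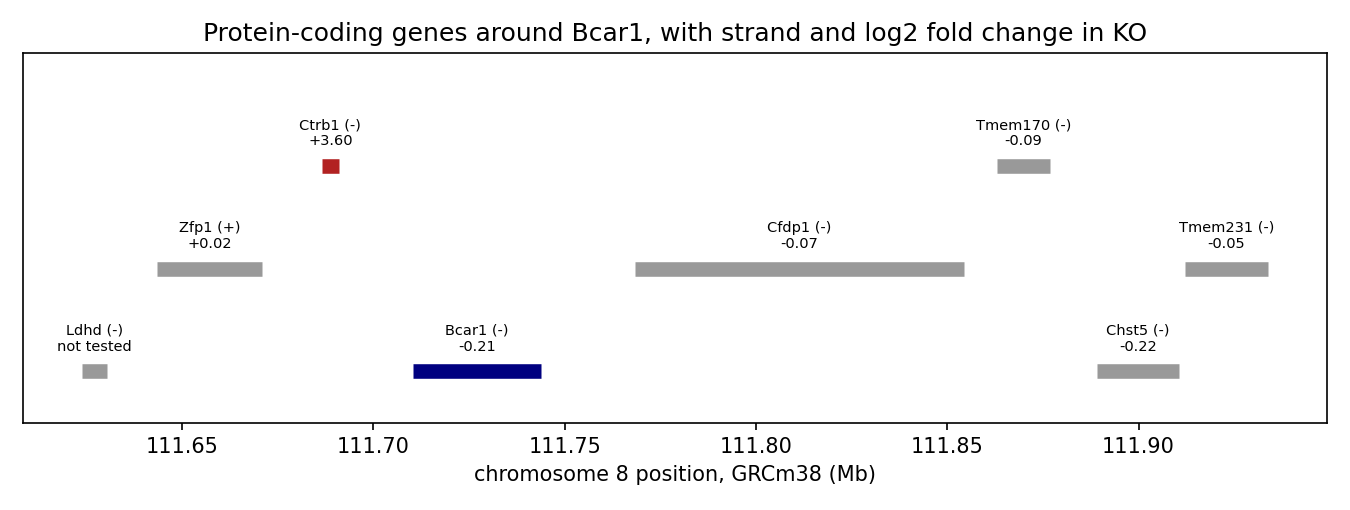
Protein-coding genes near Bcar1 on chromosome 8 (GRCm38), drawn to scale along the x axis in Mb, with strand and log2 fold change in KO where tested. Ctrb1, downstream of Bcar1, is at 3.60, and the other tested genes drawn lie between -0.22 and 0.02.

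Interferon-response genes were then counted as a list, beside a list for class I antigen presentation. Both lists were written after the values had been seen, so neither is independent evidence, and they share 8 members. Of 81 tested interferon-response genes, 28 rose and 53 did not pass, where 0.264 would be expected among 48 calls (one-sided Fisher's exact test, p = 4.37e-53). Adjusted over the list alone, 46 rose. Their median log2 fold change was 0.43, and camera gave an unadjusted p of 1.59e-71 with a preset correlation and p = 0.00269 with an estimated correlation. Ifi27 was among them, rising from 20.6 ± 1.47 to 50.9 ± 0.708 FPKM (SD, n = 3 each). Of 19 tested antigen presentation genes, 6 rose and 13 did not pass (one-sided Fisher's exact test, p = 2.29e-11), and 11 rose adjusted over the list alone. Camera gave an unadjusted p of 6.00e-29 with a preset correlation and p = 0.0128 with an estimated correlation. B2m, the light chain of class I molecules, rose from 59.8 ± 7.17 to 143 ± 16.2 FPKM, and Tap1, which carries peptides to them, from 3.33 ± 0.375 to 8.34 ± 0.957 FPKM. There were 18 higher genes in neither list, among them Ctrb1, Esr1 and Ifi27l2a. Others, named after their values were seen, were Igtp, Irgm1 and Irgm2, and Oas1b and Oas1g, relatives of the list member Oas1a. The lists are not exhaustive, so a gene outside them can still belong to the interferon response. Leukocyte markers moved in the same direction, with a list median of 0.36, 0.61 and 0.22 above the control mean in KO replicates 1 to 3, beside 0.32, 0.46 and 0.42 for interferon-response genes. The upper quartile of the log2 fold changes was 0.67 for leukocyte markers and 1.23 for interferon-response genes.

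The 1 lower gene, named after its values were seen, was Gm49380 (ENSMUSG00000111409), a predicted gene on chromosome 9 from 44066327 to 44113500 on the minus strand. It stood at 2.93, 4.66 and 4.04 FPKM in control replicates 1 to 3, was listed at 0 in KO replicates 1 and 3, and stood at 0.141 FPKM in KO replicate 2 (limma, adjusted p = 0.00119). With KO replicate 1 or KO replicate 2 left out, 2 genes were lower. A further 9 genes had no overlap between groups and a log2 fold change of -0.58 or lower, and did not pass. Of these, 4 were predicted genes or pseudogenes named after their values were seen, Gm9917, Gm13304, Gm5417 and Gm14440. Gm14440 had the lowest fold change of the 9, at 2.41 ± 0.179 FPKM in control and 0.546 ± 0.392 FPKM in KO libraries. The 5 remaining genes were Hacd1, an enzyme of fatty acid elongation, at 10.1 ± 2.37 FPKM in control and 6.13 ± 0.681 FPKM in KO libraries, and Epyc, a proteoglycan of cartilage, at 2.39 ± 0.461 and 0.989 ± 0.730 FPKM. The others were Shisa3 at 14.2 ± 4.87 and 6.84 ± 3.07 FPKM, Prph, a neuronal filament protein, at 12.1 ± 5.50 and 5.97 ± 0.660 FPKM, and Raver1 at 33.6 ± 7.66 and 22.2 ± 5.85 FPKM.

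Gene lists fixed in advance asked which processes and cell types differed. Of 35 lists tested, 4 shifted higher and 5 lower in KO in camera with a preset correlation. With an estimated correlation 0 lists passed in camera, where 4 had an unadjusted p under 0.05, and fry called 2. No member of a fixed list passed over all genes in limma with genotype alone, equal library weights and all 6 libraries. Of the members recomputed under the alternatives, Trp53inp1, Ccng1, Zmat3, Bnip3 and Gapdh passed with library weights, and Gapdh also with sex as a covariate and without KO replicate 2.

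Markers of macrophages and other leukocytes shifted higher, with 23 of 25 tested members above 0 and a median log2 fold change of 0.42 (camera, adjusted p = 5.50e-24, and adjusted p = 0.197 with an estimated correlation). Adjusted over the list alone, 15 members rose and 10 did not pass, and the list shares 0 tested members with the interferon-response list. Lyz2, a lysozyme of macrophages, was at 8.73 ± 1.35 FPKM in control and 15.6 ± 2.51 FPKM in KO libraries (SD, n = 3 each), and Adgre1, the macrophage antigen F4/80, at 1.77 ± 0.360 and 3.45 ± 0.412 FPKM.

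Genes of hypoxia and glycolysis shifted higher, with 32 of 34 members above 0 and a median of 0.20 (camera, adjusted p = 6.95e-18, and adjusted p = 0.178 with an estimated correlation). Adjusted over the list alone, 3 members rose and 31 did not pass. Bnip3, a mitophagy receptor, was at 20.5 ± 1.37 FPKM in control and 28.5 ± 2.66 FPKM in KO libraries, and Pgk1, a glycolytic kinase, at 150.2 ± 11.0 and 198 ± 22.4 FPKM. Bnip3 passed over all genes with library weights (limma, adjusted p = 0.0458, in a range over alternatives from 0.0458 to 0.658). Gapdh was at 12.6 ± 1.20 and 24.9 ± 7.93 FPKM, a value that is uncertain because the gene has many pseudogenes. It passed over all genes with library weights and without KO replicate 2 (limma, adjusted p = 0.0335 and 0.00743), in a range over alternatives from 0.00684 to 1.00.

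Genes of the p53 response and apoptosis shifted higher with a median of 0.04 and a mean of 0.11 (camera, adjusted p = 4.86e-06, and adjusted p = 0.154 with an estimated correlation), and fry gave an adjusted p of 0.0147. The median was 0.02 without control replicate 1 and 0.07 without control replicate 3. Adjusted over the list alone, 5 of 32 members rose and 27 did not pass. Ccng1 was at 13.6 ± 0.415 FPKM in control and 18.4 ± 1.35 FPKM in KO libraries, Trp53inp1 at 6.21 ± 0.128 and 8.51 ± 0.104 FPKM, and Bbc3, which encodes the death protein Puma, at 3.31 ± 0.250 and 4.85 ± 0.282 FPKM. With library weights Ccng1, Trp53inp1 and Zmat3 passed over all genes (limma, adjusted p = 0.0210, 0.0318 and 0.0340), where the highest adjusted p over alternatives was 0.573, 0.489 and 0.936.

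Genes of the G2/M phase shifted higher with a median of 0.07 (camera, adjusted p = 7.15e-06, and adjusted p = 0.969 with an estimated correlation), and 0 of 46 rose adjusted over the list alone. Psrc1, a spindle protein, was at 24.1 ± 2.14 FPKM in control and 29.3 ± 2.53 FPKM in KO libraries. The call was lost without KO replicate 3, where the median fell to 0.01 (camera, adjusted p = 0.0672, in a range over alternatives from 1.04e-09 to 0.969). Without control replicate 1 the median was 0.12.

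Skeletal muscle genes shifted lower, with all 36 below 0 and a median of -0.21 (camera, adjusted p = 5.82e-06, and adjusted p = 0.969 with an estimated correlation), and 0 passed over the list alone. Neb, the thin filament protein nebulin, was at 3.13 ± 0.186 FPKM in control and 2.29 ± 0.301 FPKM in KO libraries. The list median was as low in control replicate 1, at -0.39, as in KO replicate 1, at -0.40. The call was lost without control replicate 3, with a median of -0.08 (camera, adjusted p = 0.244, in a range over alternatives from 9.77e-18 to 0.969). The median was -0.42, -0.12 and -0.34 without control replicate 1, KO replicate 1 and KO replicate 2.

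Mitochondrially encoded genes shifted lower with a median of -0.10 (camera, adjusted p = 9.63e-04, and adjusted p = 0.185 with an estimated correlation), and fry gave an adjusted p of 0.0147. Of 15 genes, 14 were below 0 and 0 passed over the list alone. The ribosomal RNA gene mt-Rnr2 was at 151 ± 9.11 FPKM in control and 128 ± 14.1 FPKM in KO libraries, and mt-Nd4 at 1487 ± 46.5 and 1301 ± 51.1 FPKM. With quantile normalization the call was lost, with a median of -0.06 (camera, adjusted p = 0.296, in a range over alternatives from 4.54e-04 to 0.296).

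Endothelial genes shifted lower with a median of -0.16 (camera, adjusted p = 0.00109, and adjusted p = 0.969 with an estimated correlation), and 0 of 28 passed over the list alone. Egfl7 was at 44.6 ± 1.84 FPKM in control and 37.9 ± 1.71 FPKM in KO libraries, and Cldn5, a tight junction protein, at 14.4 ± 1.93 and 10.8 ± 1.08 FPKM. The call was lost without control replicate 3, with a median of -0.10 (camera, adjusted p = 0.209), and without KO replicate 2, with a median of -0.05 (camera, adjusted p = 0.375), in a range over alternatives from 4.53e-06 to 0.969. The list median was -0.35 in KO replicate 2, and in KO replicates 1 and 3 it was -0.03 and -0.07, inside the controls, which ran from -0.08 to 0.12.

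Cartilage genes shifted lower with a median of -0.73 (camera, adjusted p = 0.00132, and adjusted p = 0.969 with an estimated correlation), and 0 of 25 passed over the list alone. The list median was 0.61 in KO replicate 1, -1.32 in KO replicate 2 and -0.95 in KO replicate 3, and it ran from -0.35 to 0.49 in controls. The call was lost without control replicate 3, KO replicate 2 or KO replicate 3, with medians of -0.36, -0.33 and -0.23 (camera, adjusted p = 0.244, 0.275 and 0.354), in a range over alternatives from 7.54e-26 to 0.969. Without KO replicate 1 the median was -1.10, and with library weights it turned to 0.15. Bone genes shifted lower with a median of -0.17 (camera, adjusted p = 0.0207, and adjusted p = 0.969 with an estimated correlation), and 0 of 20 passed over the list alone. Kazald1 was at 13.1 ± 0.941 FPKM in control and 10.4 ± 1.67 FPKM in KO libraries. The bone call was lost without control replicate 1 or KO replicate 1, with medians of -0.10 and -0.05 (camera, adjusted p = 0.658 and 0.486), in a range over alternatives from 4.76e-04 to 0.969.

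**Figure D4:**
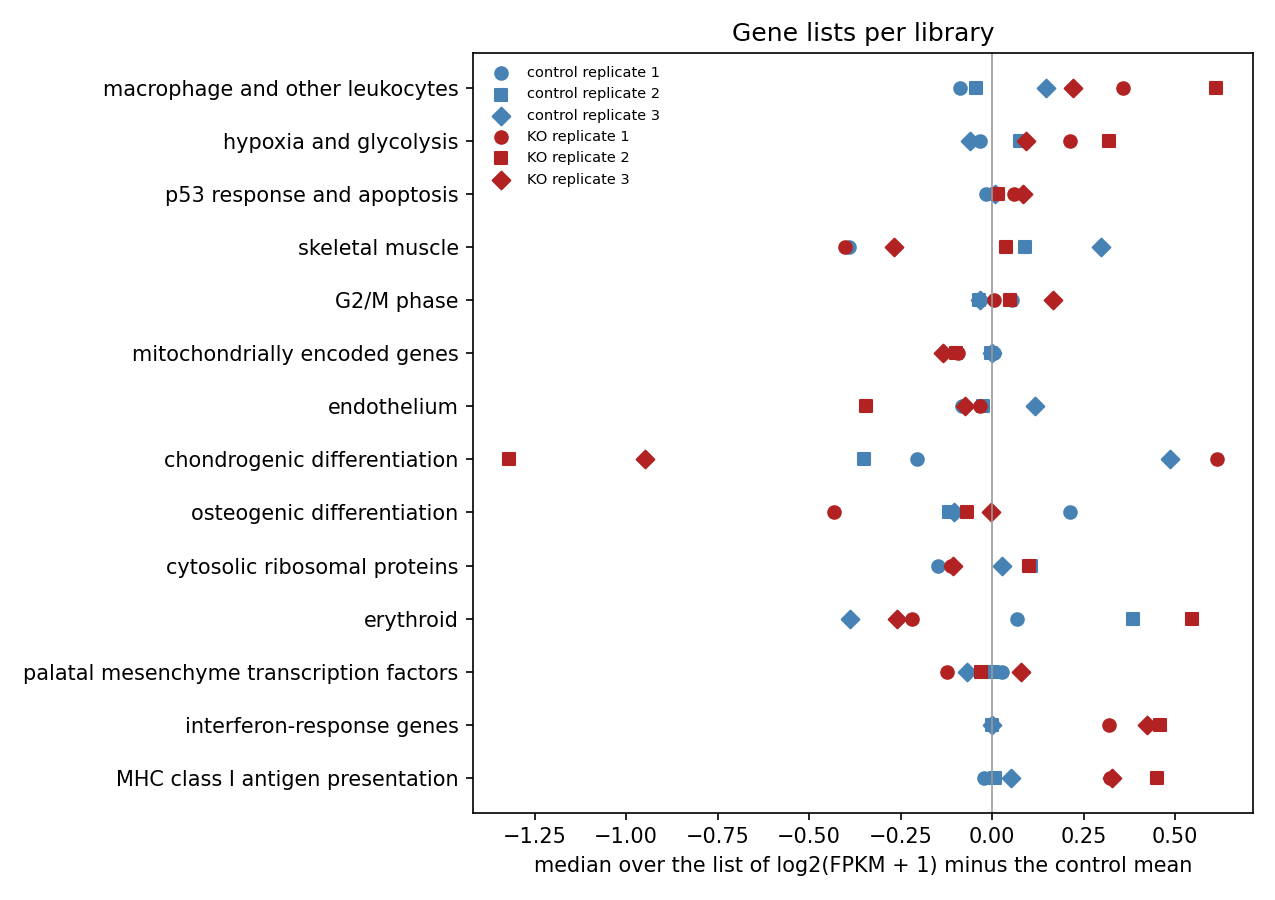
Median over each gene list of log2(FPKM + 1) minus the control mean of each gene on the x axis, 1 line of points per list, controls in blue and KO in red. KO libraries lie between 0.32 and 0.46 for interferon-response genes, while for cartilage genes they lie on both sides of the controls, from -1.32 to 0.61.

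Genes that pattern or build the palate did not pass as lists in camera. Transcription factors of the palatal mesenchyme had a median log2 fold change of -0.03 over 41 tested members (adjusted p = 0.923). Meox1 was at 4.94 ± 0.300 FPKM in control and 3.53 ± 0.581 FPKM in KO libraries (SD, n = 3 each) and Dlx1 at 33.1 ± 1.60 and 23.4 ± 5.66 FPKM, and neither passed. The adjusted p was 0.923 for the Hedgehog pathway, 0.903 for the BMP pathway, 0.903 for the TGF-beta pathway, 0.921 for the Wnt pathway, 0.923 for the FGF pathway and 0.903 for PDGF, IGF and other growth factors. Gli1 was at 46.5 ± 3.22 and 40.9 ± 3.92 FPKM, and Tgfb1 at 21.8 ± 1.01 and 17.5 ± 2.92 FPKM, and neither passed. The adjusted p was 0.332 for Cas family and adhesion signalling, 0.903 for integrins, 0.921 for the extracellular matrix, 0.723 for actin and SRF targets, 0.127 for YAP/TAZ targets and 0.921 for S phase. For the transcription factors and the Hedgehog, Wnt, FGF, growth factor, matrix and actin lists the median and mean were below 0 while camera pointed up. Camera compares the t statistics of a list, not its fold changes, with those of all other genes. For integrins, where camera also pointed up, the median was 0.03 and the mean -0.01.

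The other lists that did not pass camera covered cell types and RNA quality. The adjusted p was 0.332 for oral and palatal epithelium, 0.338 for nasal and olfactory epithelium, 0.723 for pericytes and smooth muscle, 0.901 for neurons, 0.903 for glia, 0.443 for tooth and salivary primordia and 0.0901 for erythroid cells. It was 0.157 for immediate early genes, 0.332 for the integrated stress response, 0.443 for cholesterol biosynthesis, 0.332 for histone genes, 0.654 for cytosolic ribosomal proteins and 0.658 for X inactivation and Y-linked genes. Hbb-y, an embryonic globin, was at 1878 ± 797 FPKM in control and 3354 ± 1015 FPKM in KO libraries and did not pass. Adjusted over their own lists alone, 1 gene of these lists rose, Sesn2 of the stress response, from 4.68 ± 0.101 to 6.85 ± 0.924 FPKM. For the stress response camera pointed up and the mean was 0.02, while the median was just below 0. The melanocyte list had 2 tested members and was not tested.

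The embryos differed in sex. KO replicate 2 was the only library with Xist above 0, at 61.0 FPKM, and had Ddx3y listed at 0, as in a female. The other 5 libraries had Xist listed at 0 and Ddx3y between 15.2 and 18.8 FPKM, as in males. KO replicate 2 also had the highest share of FPKM in haemoglobin genes, at 9.54%, against 4.39% to 7.99% in the others. The first principal component, with 32.0% of the variance, set control replicate 1, KO replicate 1 and KO replicate 3 apart from the other 3 libraries, so it did not follow genotype. The second, with 27.05%, separated the groups: it was between 4.28 and 16.3 in controls and between -14.6 and -5.33 in KO libraries. Chance alone separates 3 and 3 values in 10% of cases, so this does not tie the component to genotype.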

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

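The lists for interferon response and antigen presentation were chosen after the data were seen, and the alternatives before. All of the 48 higher genes that were tested kept a log2 fold change above 0 under every alternative. Except with quantile normalization, median-of-ratios scaling and rescaling to TPM this was fixed in advance, because the groups did not overlap for any called gene. Pseudocounts, library weights, the sex covariate and left-out libraries cannot reverse the sign for such genes. Filters, eBayes settings and the replicate block leave the fold change as it was. Their number stayed within 1.5 times of 48 except with the filter at a mean of 5 FPKM, which leaves 9923 genes, 25 of the 48 among them, and gave 24 higher and 0 lower genes in limma (182 lower at an unadjusted p under 0.05) and 17 interferon-response genes. Leaving out single libraries gave 32 to 48 higher and 1 to 2 lower genes, 21 to 28 interferon-response genes, 4 to 7 antigen presentation genes, 7 to 13 shifted lists and a Bcar1 log2 fold change from -0.24 to -0.13. Lower genes numbered 2 with no filter, with the filter at 0.1 FPKM and without KO replicate 1, where Gm14440 joined Gm49380, and 2 with sex as a covariate and without KO replicate 2, where Gm1943 did. The cause was not tested. Both were named after their values were seen. Of the 9 shifted lists, 0 were called with an estimated correlation and 2 with fry. The cartilage list reversed with library weights, to a median of 0.15. Bone genes were also lost with no filter and with the filter at 0.1 FPKM (adjusted p = 0.104 and 0.0686), cartilage genes with the filter at 5 FPKM (adjusted p = 0.105) and endothelial genes with library weights (adjusted p = 0.209). The filter at 5 FPKM removes Bcar1, and eBayes settings do not enter camera, so these gave no value. Only KO replicate 2 was female, so the sex covariate amounts to leaving it out. The replicate number as a block gave 41 higher genes, 38 of them among the 48, and 1 lower gene, Bcar1 at -0.21, 25 interferon-response genes, 6 antigen presentation genes and 10 shifted lists. Deviations of same-numbered libraries correlated across genes at 0.0192, 0.305 and -0.241, and control replicate 1 correlated best with KO replicate 3. These values do not show that the numbers pair the libraries, but with 3 libraries per group they cannot exclude it. With 3 libraries per group and unknown depth, small changes and low genes are poorly resolved.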

Other observations

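The tests of leukocytes, of the female embryo, of exocrine tissue, of transcription from Bcar1 into Ctrb1 and of receptor sequence in the transgene were chosen after the results were seen. The interferon genes looked at, among them Ifnb1 and Ifng, were listed at 0 in all 6 libraries. Of 17 tested genes for interferons, their receptors and nucleic acid sensors, 1 was called, the RNA sensor Ddx58, which rose from 3.17 ± 0.148 to 7.46 ± 0.444 FPKM (SD, n = 3 each; limma, adjusted p = 0.00204). Adjusted over the list alone, 2 rose, Ddx58 and Adar, the latter with a log2 fold change of 0.45 ± 0.08 (SE). Sensors with a mean under 1 FPKM, Ifih1 among them, were not tested. The control and KO means were 0.465 and 1.47 FPKM for Ifih1 and 0.0406 and 0.888 FPKM for Zbp1. They were 0.366 and 0.588 FPKM for Tlr7, 0.581 and 0.73 FPKM for Tlr3, and 0.260 and 0.307 FPKM for Tlr9. The median log2 fold change of the list was 0.02, and camera gave an unadjusted p of 0.00766 with a preset correlation and p = 0.199 with an estimated correlation.

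The 48 genes higher in KO were weighed first. A larger share of leukocytes would raise no gene by more than its own markers. The median log2 fold change of the 48 genes lay 0.4422 above the highest leukocyte marker, Cd52. With a pseudocount of 0.01 it was 1.94 (95% bootstrap interval 1.60 to 2.32) against 1.29 for the highest marker there. However, the 48 genes were picked for their rise in the same libraries, and 0 leukocyte markers were among them. A higher median was thus favoured in advance. A call did not require a rise above that marker, since the smallest called rise was 0.61. Of the 48 genes, 44 lay above the highest marker, and for 34 the 95% interval lay above it. For these 34 genes this argues against a larger share of the leukocytes that the markers cover as the sole cause. The spread of the marker itself was not counted. The comparison does not decide whether leukocytes were part of the cause, and it leaves open which cells responded. Without the female KO replicate 2, 40 of the 48 genes were still called, which argues against the sex of that embryo as the whole cause. All 48 kept a log2 fold change above 0, but this was fixed in advance, since the groups did not overlap for any called gene. The presence of the Cre transgene and the loss of p130Cas cannot be told apart, since 0 control libraries carried Cre, and either may underlie the increase. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: genotype gave 49 genes, and the highest other split gave 548, so 2 splits gave as many. That other split, control replicate 1, KO replicate 1 and KO replicate 3 against the rest, points to a structure of the samples apart from genotype, and it shared 0 genes with the genotype calls and held 19 of 86 ribosomal protein genes and 17 of 36 muscle genes.

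The second pattern was Ctrb1. Exocrine tissue would bring the other abundant acinar enzymes. Of the 30 other genes of the acinar list, which also holds some genes that are not enzymes, 24 were listed at 0 in all KO libraries. This argues against exocrine tissue as the source. This count replaced an earlier test, which compared the levels of these genes with Ctrb1 and did not decide, since its bound was met by less than the spread. Transcription from the recombined Bcar1 allele running on into Ctrb1 is a candidate explanation that stays open. The KO mean was 16.2 FPKM for Ctrb1 and 1.56 FPKM for Bcar1, a gap that such transcription would have to account for. The largest absolute log2 fold change among the 14 other tested neighbours was 0.2184, which does not decide it, and reads that would join both genes were not analysed here.

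The third pattern was Esr1, listed at 0 in all control libraries and at 5.284 FPKM or more in KO libraries. A candidate explanation is that the Cre transgene carries oestrogen receptor sequence, as some inducible forms of Cre do, and it stays open because the labels do not give the form of Cre and reads along the gene were not analysed here. A gain of receptor activity was not decided either: of 16 tested oestrogen receptor targets 0 passed in limma, 0 also had an unadjusted p under 0.05, and their median log2 fold change was -0.01035 (95% bootstrap interval -0.107 to 0.0829). Camera gave an unadjusted p of 0.469 for these targets, and p = 0.481 with an estimated correlation.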
